A study of Homo sapiens with 8 samples.

How the data were processed

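RNA was measured by sequencing in MCF-7M cells, a line whose parental line is MCF-7, an established line of luminal breast cancer cells. Cells had been transfected with small interfering RNA (siRNA) by lipofectamine, and total RNA was prepared for sequencing with a TruSeq RNA kit. The labels give 4 groups with 2 replicates each, 8 libraries in all: non-targeting siRNA (NT), siRNA against LIN28, siRNA against hnRNP A1, and both siRNAs together. The labels do not say whether the replicates of a group were separate cultures, so every p-value measures only the spread between these samples.

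The deposited values are FPKM (fragments per kilobase of transcript, scaled by the mapped fragments of the library) for 40723 RefSeq transcripts in each library. The submitters' processing notes name TopHat2 2.0.4, Cufflinks 2.0.2 and the genome build hg19, without options or filters. The values were not rescaled before the tests. A reference table of RefSeq genes on a later build served only to give each transcript its gene symbol, and no positions are given because the builds differ. It matched 39397 transcripts, which is 96.7% of them and 98.5% to 98.8% of the summed FPKM of a library. The values of the transcripts of each gene were added, which gave 22965 genes, 7757 of them with more than 1 transcript. The plan had expected values per gene, and this sum was chosen when the files showed values per transcript.

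The files state no read counts, so the absolute depth is unknown and no counting interval or detection limit can be given. Low values of genes with 1 transcript stand in small whole-number ratios between libraries, and these gave depths relative to NT replicate 1 from 0.770 (LIN28 siRNA replicate 2) to 1.06 (hnRNP A1 siRNA replicate 1).

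The values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a variance trend). The 11686 genes with a mean of at least 1 FPKM over the 8 libraries were tested, with 1 mean per group and all 8 libraries in 1 fit. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no fold minimum. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes of low FPKM. Errors of fold changes are the standard errors of the fit, and errors of FPKM are standard deviations (SD) over the 2 libraries of a group. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the figures.

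The 7 comparisons were each knockdown against NT, both siRNAs against each single one, hnRNP A1 siRNA against LIN28 siRNA, and the interaction, which is the departure of the double knockdown from the sum of both single knockdowns on the log2 scale. The comparisons, tests, 23 gene lists and the rule for named genes were fixed before the data were examined. The rule took, in each comparison with NT, the 10 largest rises and the 10 largest falls among called genes whose 2 libraries both lay beyond both NT libraries, and the 5 largest in each direction in the other comparisons. It added LIN28A, LIN28B, HNRNPA1, its relatives HNRNPA1L2, HNRNPA2B1 and HNRNPA3, the splicing-regulated genes ENAH and PKM, and up to 4 members of each list with the smallest p. The lists cover the hnRNP family, SR proteins and other splicing regulators, published let-7 targets, microRNA processing, estrogen response, epithelial and mesenchymal markers, G1/S and G2/M genes, p53 targets, interferon response, the integrated stress and unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, replication-dependent histones, immediate early genes, and markers of luminal mammary epithelium, basal mammary epithelium, fibroblasts, leukocytes and endothelium. The histone list was fixed as a check on RNA selection and the immediate early list as a check on handling. Of the 756 list members, 750 were found in the files.

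Lists with at least 5 measured members, 19 of the 23, were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each was tested again with an estimated correlation, and with fry, which asks whether a list's own genes move on balance in 1 direction and does not compare them with other genes. Transcript shares were tested with limma on the log2 ratio of a transcript's FPKM + 1 to the FPKM + 1 of the rest of its gene. The variance trend followed the gene's FPKM. Genes had a mean of at least 5 FPKM and were measured in every library. Transcripts had a mean share of at least 5%, with at least 5% left to the rest. Percentages printed beside the adjusted p of that test are the shares themselves, not the ratios. That test and 4 further gene lists were added after the values had been seen.

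The procedure was tested on simulated data with the size of the LIN28 siRNA comparison. Of 50 genes changed by each factor, the limma test recovered 7 at 1.2-fold, 32 at 1.5-fold, 42 at 2-fold and 48 at 4-fold, and it called 4 unchanged genes. It called 0 genes in a simulated comparison with no change. A list raised by 1.2-fold was found by all 3 list tests, and 0 other lists were called. The simulated genes varied independently of each other, so this does not show how the list tests behave with correlated genes.

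The alternatives were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, quantile normalization, median ratio scaling, 2 other variance models, a fit of only the groups compared, the replicate number as a block, a fold minimum of 1.5, and leaving out each library in turn. Where the library left out belongs to a group that is not compared, the fold change stays the same and only the estimate of the spread changes. Leaving out short non-coding RNAs, or genes listed at 0 in 1 library beside at least 10 FPKM in its replicate, was added after the values had been seen. The replicate number was not used as a pairing in the tests reported, because nothing in the labels says what it stands for. If replicates of 1 number share a difference, leaving out 1 library sets part of it between the groups compared.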

Results

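The series holds FPKM of RefSeq transcripts from 8 RNA libraries of MCF-7M breast cancer cells, summed here to genes. There were 2 libraries in each of 4 groups: non-targeting siRNA (NT), LIN28 siRNA, hnRNP A1 siRNA, and both siRNAs. LIN28A binds RNA and blocks the maturation of let-7 microRNAs, and hnRNP A1 is an RNA-binding regulator of splicing. Between 11442 and 11685 genes reached 1 FPKM per library, and the summed FPKM of a library lay between 352758 and 379348. Read counts are not given, so depth is known only relative to other libraries, from 0.770 to 1.06 of NT replicate 1. Markers of luminal mammary epithelium were expressed, with all 10 tested, among them KRT19 at a mean of 1631 FPKM. Markers of other cell types were scarce: 1 of 12 fibroblast markers reached the filter (COL1A1, mean 9.46 FPKM), 4 of 12 basal epithelial (highest ITGB4, 37.4 FPKM), 2 of 10 endothelial (highest ENG, 11.7 FPKM) and 0 of 12 leukocyte markers (highest CD68, 0.454 FPKM). These 4 lists had too few measured members for a list test.

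The first question was whether each siRNA lowered its target. LIN28A stood at 42.1 ± 0.436 FPKM (SD, n = 2) in NT and 14.0 ± 0.853 FPKM with LIN28 siRNA, a log2 fold change of -1.52 ± 0.06 (SE; limma adjusted p = 0.00021). With both siRNAs it stood at 14.6 ± 0.728 FPKM (log2 fold change -1.47, adjusted p = 0.00024), and with hnRNP A1 siRNA at 43.1 ± 0.0279 FPKM (0.04, adjusted p = 0.77). HNRNPA1 fell from 324 ± 7.17 FPKM in NT to 163 ± 5.22 FPKM with hnRNP A1 siRNA (log2 fold change -0.99 ± 0.06, adjusted p = 0.0006) and to 184 ± 3.62 FPKM with both siRNAs (-0.81 ± 0.06, adjusted p = 0.0012). With LIN28 siRNA it stood at 334 ± 16.9 FPKM, a log2 fold change of 0.05 (adjusted p = 0.72), or -0.0047 without LIN28 siRNA replicate 1 (adjusted p = 0.99). LIN28B, the close relative of LIN28A, had a mean of 0.0027 FPKM and was not tested. Genes of the HNRNPA1 family with near-identical sequence also fell with hnRNP A1 siRNA, HNRNPA1P10 by 0.93 ± 0.07 and HNRNPA1L2 by 0.55 ± 0.08 on the log2 scale, and their reads cannot be fully separated from those of HNRNPA1. The HNRNPA1L2 call was lost without hnRNP A1 siRNA replicate 1 or 2 or NT replicate 1 or 2 (adjusted p up to 0.080, without hnRNP A1 siRNA replicate 2).

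**Figure D1:**
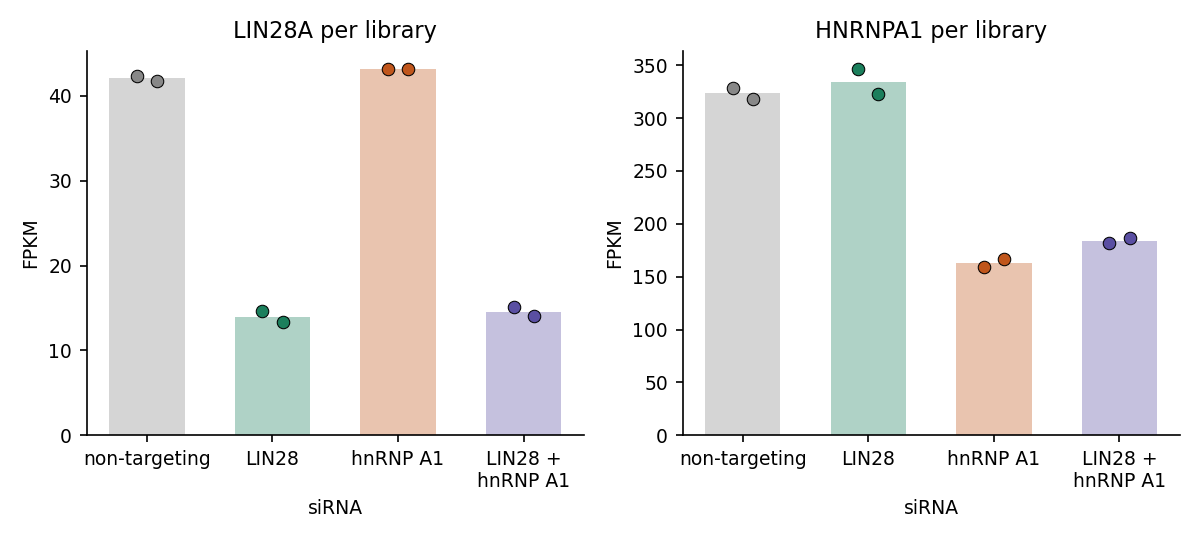
FPKM of LIN28A and HNRNPA1 in each of the 8 libraries (points) with the mean of each group (bars, n = 2). LIN28A lies at 13.4 to 15.1 FPKM in the 4 libraries with LIN28 siRNA and HNRNPA1 at 159 to 187 FPKM in the 4 with hnRNP A1 siRNA.

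LIN28 siRNA against NT asked which genes change when LIN28 is lowered. Among genes measured above 0 in every library, interferon-induced antiviral genes had the largest rises. IFIT3 stood at 10.8 ± 1.99 FPKM in NT and 51.7 ± 8.01 FPKM with LIN28 siRNA (SD, n = 2; log2 fold change 2.16 ± 0.14, adjusted p = 0.0011), IFIT2 rose by 2.09 and MX1 rose from 173 ± 9.43 to 379 ± 2.38 FPKM (1.13 ± 0.06). The chemokine gene CCL5 rose by 1.64 ± 0.11 and LGALS3BP, a secreted galectin-binding glycoprotein, by 1.48 ± 0.09. Of the 39 measured members of the interferon response list, 36 rose (39 adjusted over the list alone), with a median log2 fold change of 0.97 and a range from 0.29 (EIF2AK2) to 2.16 (IFIT3). ISG20, MX2 and EIF2AK2 did not pass. All 39 lay above both NT libraries in both LIN28 siRNA libraries. The list passed camera (adjusted p = 1.0e-44) and fry (adjusted p = 0.00046), and had an adjusted p = 0.090 with an estimated correlation. The count was 22 without LIN28 siRNA replicate 2 and 17 when only the compared groups were fitted. IFNL1, a type III interferon, rose from 0.388 ± 0.0242 to 3.46 ± 0.801 FPKM (log2 fold change 1.67), but missed the threshold without NT replicate 2 (adjusted p = 0.054) or LIN28 siRNA replicate 2 (0.058).

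Beside LIN28A, MAN1A1, a mannosidase of N-glycan processing, had the largest fall among genes measured above 0 in every library, from 46.0 ± 4.27 to 22.5 ± 2.17 FPKM (SD, n = 2; log2 fold change -1.0 ± 0.10, adjusted p = 0.0054, or 0.067 when only the compared groups were fitted). SYTL2 (-0.93), LONRF2 (-0.83), PPM1F (-0.80), the growth factor-binding gene IGFBP5 (-0.78), PEG10 (-0.69) and FAM225B (-0.69) also fell. Among splicing regulators 2 of 47 fell, PTBP3 by 0.49 and RBFOX2 by 0.45, and among the 26 measured members of the hnRNP family HNRNPA3 fell by 0.35. TJP1, which codes for the tight junction protein ZO-1, fell by 0.65 as 1 of 33 epithelial markers, and the progesterone receptor gene PGR (-0.44) and OLFM1 (-0.40) fell as 2 of 36 estrogen response genes. ACTA2 rose by 0.51 as 1 of 10 mesenchymal markers. The splicing-regulated genes ENAH (0.17, adjusted p = 0.45) and PKM (0.09, adjusted p = 0.46) did not pass at the level of the gene. CYFIP2 (-0.56) and PLK2 (-0.36) fell as 2 of 30 p53 targets, and ATF3 (0.34), which is in the stress response and immediate early lists, and KLF4 (0.56) rose. Short nucleolar RNAs SNORA5B (166 and 95.4 FPKM) and SNORA71D (61.6 and 71.4 FPKM) were measured in both LIN28 siRNA libraries and listed at 0 in both NT libraries. SNORA62 (54.7 and 142 FPKM in NT) and SNORA20 (79.5 and 75.4 FPKM in NT) were listed at 0 with LIN28 siRNA. Zeros beside high values were frequent among short RNAs, also between replicates of a group, so a listed 0 is not evidence of absence. Leaving out a library with hnRNP A1 siRNA or both siRNAs does not alter these fold changes, only the estimate of their spread. Of the 37 named genes that passed, 15 also passed without each of the 8 libraries in turn. The other 22, among them every called gene named here except MAN1A1, LIN28A and the short RNAs, missed the threshold without at least 1 library, from 15 without either hnRNP A1 siRNA replicate to 21 without NT replicate 2 or LIN28 siRNA replicate 2 (adjusted p up to 0.263).

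The let-7 target list was lower by camera (adjusted p = 0.0052), with a median of -0.10 over 24 members, of which TGFBR1 (-0.31) and PLAGL2 (-0.38) fell (5 adjusted over the list alone). It had an adjusted p = 0.87 with an estimated correlation, and its call was lost without NT replicate 2 (0.079) or LIN28 siRNA replicate 1 (0.059). G1/S genes were higher by camera (adjusted p = 0.0060; median 0.17, 0 of 39 rose), as were hypoxia and glycolysis genes (0.031; median 0.11, with ANGPTL4 rising by 0.56 as 1 of 34) and oxidative phosphorylation genes (0.0060; median 0.08, 0 of 73 rose). These 3 lists each had an adjusted p = 0.87 with an estimated correlation. A difference shared by replicates of 1 number, which was not modelled, would enter the comparisons without 1 library that follow. The G1/S call was lost without NT replicate 1 (adjusted p = 0.59) or LIN28 siRNA replicate 2 (0.55), the hypoxia call without NT replicate 2 (0.44) or LIN28 siRNA replicate 1 (0.47), and the oxidative phosphorylation call without NT replicate 2 (0.079) or LIN28 siRNA replicate 1 (0.99). TGFBR1 and PLAGL2 missed the threshold without any 1 of the 8 libraries, and ANGPTL4 without any 1 of the NT, LIN28 siRNA or double-siRNA libraries (adjusted p up to 0.210). Of the lists that did not pass, microRNA processing had a median of -0.05 (adjusted p = 0.19), G2/M genes 0.02 (0.72), cholesterol synthesis -0.004 (0.55), ribosomal proteins -0.02 (0.13), histones -0.17 (0.26; H3C10 rose by 0.51, but not without any 1 of the 8 libraries), immediate early genes 0.11 (0.11) and luminal markers 0.08 (0.34). The estrogen response list (adjusted p = 0.13), the p53 target list (0.62) and the stress response list (0.42) did not pass either, nor did the epithelial (0.55) and mesenchymal markers (0.70), the hnRNP family (0.41) or the other splicing regulators (0.25).

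In all, 334 of 11686 genes were called between LIN28 siRNA and NT, 188 higher and 146 lower, and 110 differed by at least 1.5-fold, 89 of them higher. With quantile normalization 161 were higher and 176 lower, so which direction had more calls depended on the scaling. Leaving out 1 of the 8 libraries gave from 68 calls (without LIN28 siRNA replicate 1) to 152 (without hnRNP A1 siRNA replicate 2), and fitting only the compared groups gave 44.

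**Figure D2:**
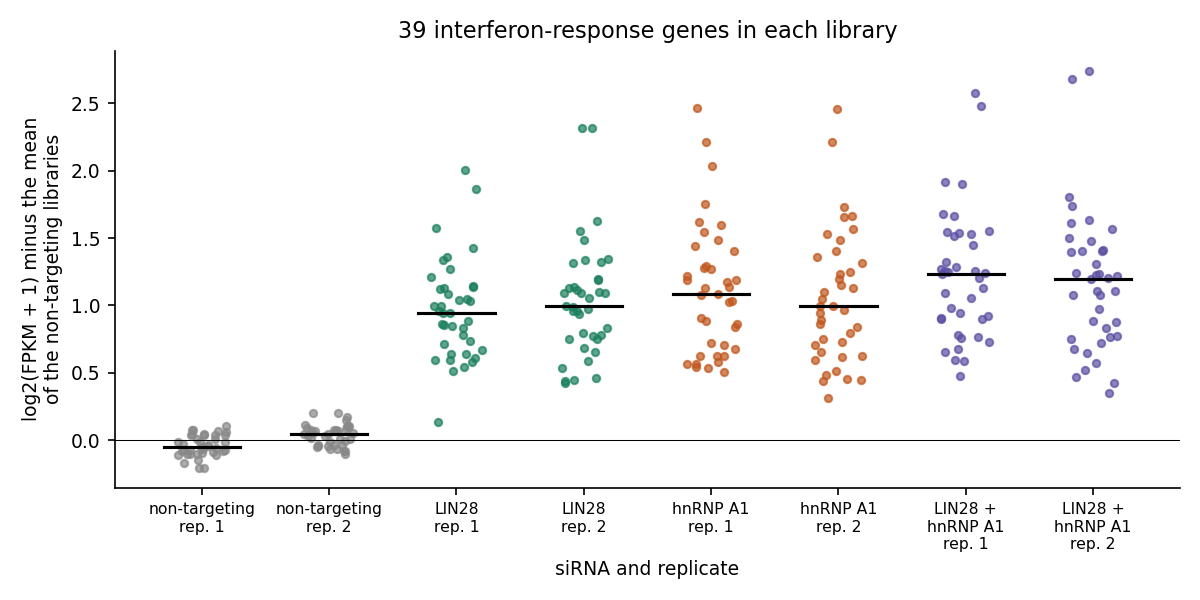
Log2 fold change against the NT mean, on the log2(FPKM + 1) scale, of the 39 measured interferon response genes in each of the 8 libraries. All 39 lie above both NT libraries in every library with LIN28 siRNA, hnRNP A1 siRNA or both.

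hnRNP A1 siRNA against NT asked which genes change when hnRNP A1 is lowered. Among genes measured above 0 in every library, interferon-induced genes again had the largest rises, with LGALS3BP rising from 11.5 ± 1.14 to 71.5 ± 0.162 FPKM (SD, n = 2; log2 fold change 2.54 ± 0.09, adjusted p = 8.0e-05), IFIT3 by 2.46 ± 0.14, IFITM3 by 2.21 ± 0.14 and IFI44L by 1.88 ± 0.11. Of the 39 interferon response genes, 38 rose (39 adjusted over the list alone), with a median of 1.04, and ISG20 (0.43) did not pass. Both hnRNP A1 siRNA libraries lay above both NT libraries in all 39. The list passed camera (adjusted p = 9.9e-37) and fry (0.00033), and had an adjusted p = 0.129 with an estimated correlation. The count was 23 when only the compared groups were fitted. IFNL1 rose by 1.67 (adjusted p = 0.066 when only the compared groups were fitted). LAMP3 rose by 1.71 ± 0.28, but missed the threshold without NT replicate 2 (adjusted p = 0.058) or either hnRNP A1 siRNA replicate (up to 0.082).

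The largest fall among genes measured above 0 in every library was that of HMGCLL1, which codes for a lyase of ketone body formation, from 2.76 ± 0.281 to 0.673 ± 0.0635 FPKM (log2 fold change -1.17 ± 0.08, adjusted p = 0.0011), followed by HNRNPA1 itself. ATP6V1C1, a subunit of the vacuolar proton pump, fell from 33.4 ± 1.32 to 17.6 ± 0.0759 FPKM (-0.89 ± 0.05, adjusted p = 0.0006). LONRF2 (-0.95), the glutamine synthetase gene GLUL (-0.94), SYTL2 (-0.94) and CSF1 (-0.75) also fell. FAS, the death receptor gene, rose from 3.66 ± 0.359 to 8.42 ± 0.398 FPKM (1.02 ± 0.08, adjusted p = 0.0016) as 1 of 3 of the 30 p53 targets that rose, with POLH (0.49) and PMAIP1 (0.46). CDH3, which codes for P-cadherin, rose by 0.90 ± 0.06, and LSR (0.49) rose while CDS1 (-0.38) and ELF3 (-0.35) fell among 33 epithelial markers. ACTA2 (0.91 ± 0.07) and ITGA5 (0.66) rose and TWIST1 (-0.50) fell among 10 mesenchymal markers. In the hnRNP family HNRNPA0 fell by 0.57 ± 0.07 (adjusted p = 0.067 when only the compared groups were fitted), HNRNPUL1 (-0.31) and FUS (-0.32) fell, and HNRNPA3 (0.33) was 1 of 2 that rose; HNRNPA2B1 had 0.21 (adjusted p = 0.078). MBNL1 (0.40) and QKI (0.32) rose among 47 other splicing regulators. NRIP1 (0.47) and RET (0.41) rose among 36 estrogen response genes, and PGR (-0.39) was 1 of 3 that fell. KLF4 rose by 0.48. SNORD94 was at 54.1 and 59.5 FPKM with hnRNP A1 siRNA and listed at 0 in NT, while SNORD22 (109 and 401 FPKM in NT) and SNORA20 (79.5 and 75.4 FPKM in NT) were listed at 0 with hnRNP A1 siRNA. Of the 58 named genes that passed, 21 also passed without each library in turn, among them HMGCLL1, HNRNPA1, HNRNPA1P10, ATP6V1C1, FAS, CDH3, ACTA2 and HNRNPA0. The other 37 all missed the threshold without hnRNP A1 siRNA replicate 2, and from 9 (without LIN28 siRNA replicate 2) to 35 (without NT replicate 2) of them without each of the other libraries (adjusted p up to 0.212).

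Cytosolic ribosomal protein genes were lower by camera (adjusted p = 4.4e-10), with a median of -0.15 over 77 members, of which RPS3A (-0.30) and RPL4 (-0.25) fell (0 adjusted over the list alone). Replication-dependent histone genes were lower (adjusted p = 0.0012), with a median of -0.37 over 13 members, of which H4C14 (-0.55) fell (3 adjusted over the list alone). That list was fixed as a check on RNA selection, and whether RNA selection differed was not tested. Hypoxia and glycolysis genes were higher (adjusted p = 0.010; median 0.14), and 5 of 34 rose (8 adjusted over the list alone), among them P4HA2 (0.50), SLC2A1 (0.46), EGLN3 (0.67) and PFKFB3 (0.52). G1/S genes were higher (adjusted p = 0.0048; median 0.23), and SLBP (0.38) and CCNE2 (0.45) rose among 39 (0 adjusted over the list alone). These 4 lists each had an adjusted p = 0.85 with an estimated correlation. The hypoxia call was lost without NT replicate 2 (adjusted p = 0.24) or hnRNP A1 siRNA replicate 1 (0.071), and the G1/S call without NT replicate 1 (0.36) or hnRNP A1 siRNA replicate 2 (0.13). Every member of these and the following lists named here missed the threshold without hnRNP A1 siRNA replicate 2 (adjusted p up to 0.212). Cholesterol synthesis genes had a median of 0.11 (adjusted p = 0.12), with INSIG1 (0.53), HMGCS1 (0.36) and STARD4 (0.44) the 3 of 24 that rose. The let-7 target list had a median of 0.07 (adjusted p = 0.95), with PLAGL2 rising by 0.48 and CCND1, the cyclin D1 gene, falling by 0.43. The remaining lists did not pass: hnRNP family (adjusted p = 0.21), other splicing regulators (0.31), microRNA processing (0.23), estrogen response (0.95), epithelial (0.58) and mesenchymal markers (0.95), G2/M genes (0.87), p53 targets (0.21), stress response (0.87), oxidative phosphorylation (0.87, with SDHA rising by 0.28), immediate early genes (0.87) and luminal markers (0.70).

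In all, 1017 genes were called between hnRNP A1 siRNA and NT, 640 higher and 377 lower, and 190 differed by at least 1.5-fold, 156 of them higher. With quantile normalization the counts were 475 higher and 477 lower, so the excess of rises depended on the scaling. Leaving out 1 of the 8 libraries gave from 140 calls (without hnRNP A1 siRNA replicate 2) to 648 (without LIN28 siRNA replicate 1), and fitting only the compared groups gave 86.

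**Figure D3:**
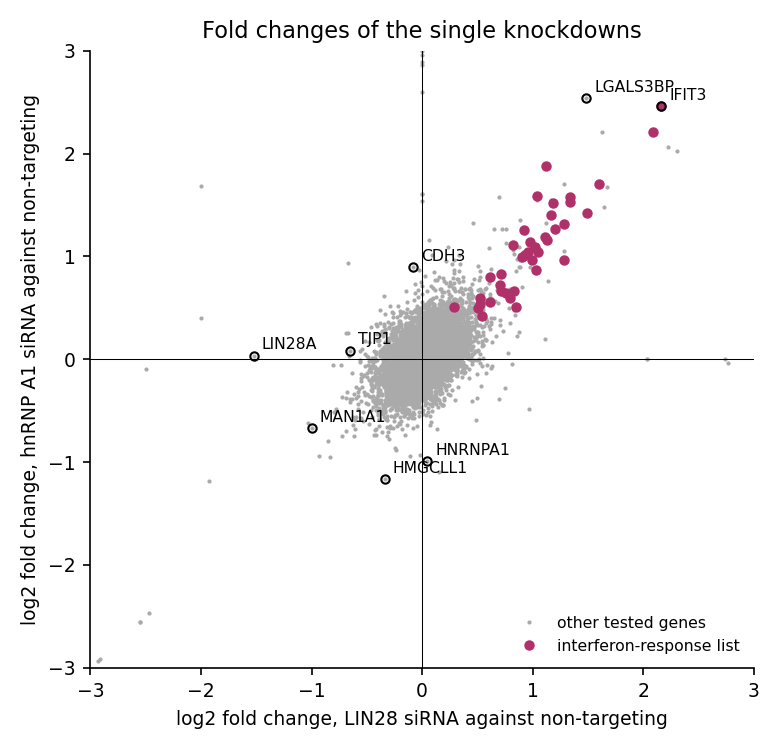
Log2 fold change against NT on the log2(FPKM + 1) scale with LIN28 siRNA (horizontal) and hnRNP A1 siRNA (vertical). Of the tested genes 11616 are plotted as points and 70 lie beyond the axes. Interferon response genes lie at positive values on both axes, and LIN28A and HNRNPA1 each lie low on 1 axis.

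Both siRNAs against NT asked which genes change when LIN28 and hnRNP A1 are lowered together. IFIT3 rose to 71.4 ± 3.57 FPKM from 10.8 ± 1.99 FPKM (SD, n = 2; log2 fold change 2.63 ± 0.14, adjusted p = 0.00031), IFIT2 by 2.61 ± 0.15, LGALS3BP by 2.45 ± 0.09, IFNL1 by 2.17 ± 0.18 and CCL5 by 1.58 ± 0.11. Of the 39 interferon response genes, 38 rose (39 adjusted over the list alone), with a median of 1.2, and ISG20 (0.47) did not pass. All 39 lay above both NT libraries in both libraries. The list passed camera (adjusted p = 1.8e-45) and fry (0.00023), and had an adjusted p = 0.087 with an estimated correlation. LAMP3 rose by 1.69 ± 0.28, but missed the threshold without NT replicate 2 or either replicate with both siRNAs (adjusted p up to 0.159).

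HMGCLL1 (-1.05 ± 0.08), ATP6V1C1 (-0.79 ± 0.05) and RASL11B (-0.79 ± 0.08) fell beside LIN28A and HNRNPA1. MAN1A1 (-0.86) and the histone gene H2BC8 (-0.80) fell but missed the threshold without replicate 2 of both siRNAs (adjusted p = 0.065 for each), and SYTL2 (-0.98) and LONRF2 (-0.92) without NT replicate 2 or either replicate with both siRNAs. SNORA20 was listed at 0 in both libraries beside 79.5 and 75.4 FPKM in NT. FAS rose by 0.88 ± 0.08, with POLH (0.42) and PMAIP1 (0.48), and PLK2 (-0.31) fell among 30 p53 targets. CDH3 rose by 0.59 ± 0.06 and ACTA2 by 0.64 ± 0.07, and each missed the threshold without replicate 1 of both siRNAs (adjusted p = 0.063 and 0.070). TWIST1 fell by 0.39. HNRNPA0 (-0.44), FUS (-0.30) and HNRNPA1L2 (-0.44) fell, and MBNL1 (0.38) rose. TGFBR1 (-0.30), CASP3 (-0.31) and CCND1 (-0.43) fell among 24 let-7 targets. NRIP1 (0.45) rose among 36 estrogen response genes, and PGR (-0.41) and OLFM1 (-0.36) were among the 3 that fell. INSIG1 (0.44) and STARD4 (0.53) rose among 24 cholesterol genes, and KLF4 rose by 0.63. Of the 48 named genes that passed, 18 also passed without each library in turn. The other 30 missed the threshold without at least 1 library, from 12 without any 1 of the single-siRNA libraries to 28 without replicate 1 of both siRNAs (adjusted p up to 0.262).

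Hypoxia and glycolysis genes were higher by camera (adjusted p = 0.00053; median 0.19), and 4 of 34 rose (9 adjusted over the list alone): SLC2A1 (0.43), EGLN3 (0.63), ENO2 (0.41) and P4HA2 (0.40). G1/S genes were higher (adjusted p = 0.0017; median 0.19), with SLBP (0.36) rising as 1 of 39 (3 adjusted over the list alone). Ribosomal protein genes were lower (adjusted p = 1.3e-09; median -0.15), with RPS3A (-0.31) falling as 1 of 77, and histone genes were lower (0.0038; median -0.34), with 0 of 13 falling (4 adjusted over the list alone). These 4 lists each had an adjusted p = 0.91 with an estimated correlation. The G1/S call was lost without NT replicate 1 (adjusted p = 0.31) or replicate 2 of both siRNAs (0.12), and the histone call without NT replicate 1 (0.073). The 6 members named here missed the threshold without NT replicate 2 or either replicate with both siRNAs, SLC2A1 also without NT replicate 1, and ENO2, P4HA2, SLBP and RPS3A without any 1 of the 8 libraries (adjusted p up to 0.262). The lists that did not pass were the hnRNP family (adjusted p = 0.25), other splicing regulators (0.17), let-7 targets (0.39), microRNA processing (0.17), estrogen response (0.88), epithelial (0.83) and mesenchymal markers (0.88), G2/M genes (0.64), p53 targets (0.19), stress response (0.43), cholesterol synthesis (0.37), oxidative phosphorylation (0.64), immediate early genes (0.56) and luminal markers (0.64). In all, 589 genes were called, 371 higher and 218 lower, and 156 differed by at least 1.5-fold, 127 of them higher. Leaving out 1 of the 8 libraries gave from 100 calls (without replicate 1 of both siRNAs) to 363 (without hnRNP A1 siRNA replicate 2), and fitting only the compared groups gave 100.

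**Figure D4:**
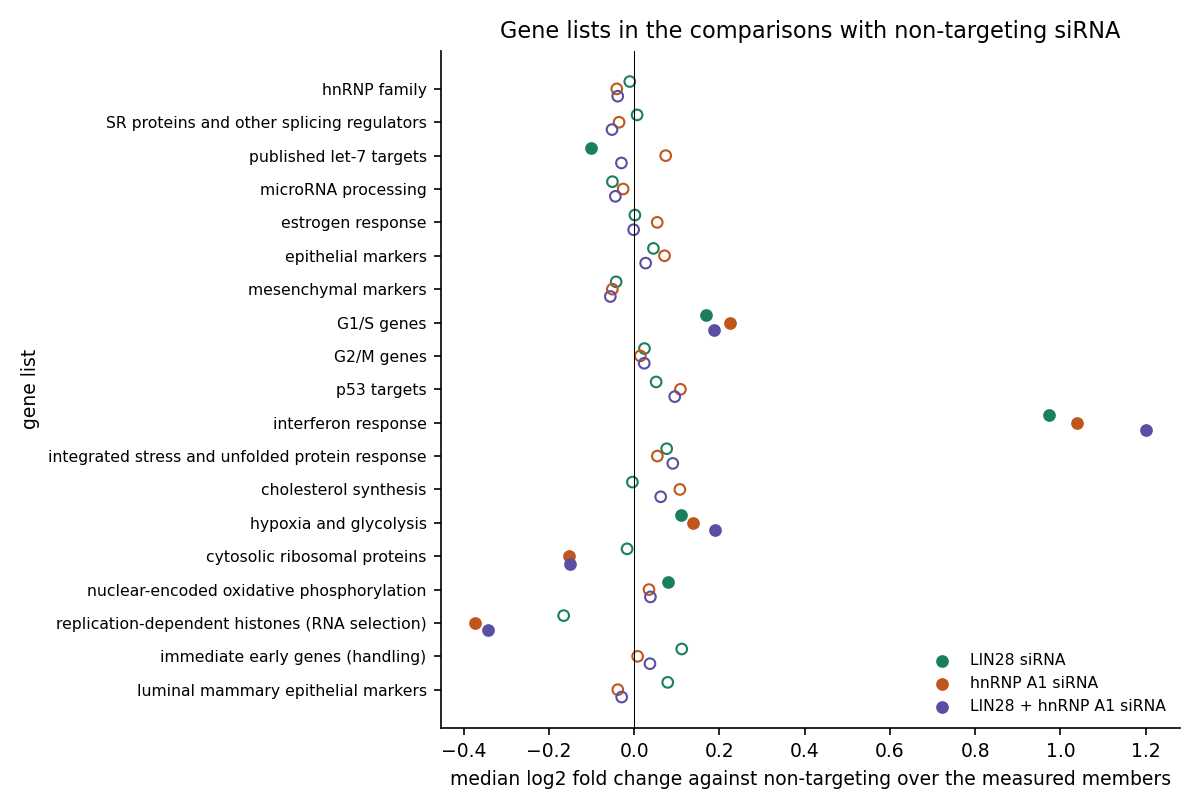
Median log2 fold change against NT of the measured members of the 19 tested gene lists, with LIN28 siRNA, hnRNP A1 siRNA and both siRNAs. Filled points passed camera at the preset correlation. The interferon response list lies at 0.97 to 1.2, and the other lists between -0.37 and 0.23.

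The overlap of the single knockdowns asked whether LIN28 and hnRNP A1 siRNA change the same genes in the same direction. They shared 184 calls in the same direction, 129 higher and 55 lower, and 36 of the 129 were interferon response genes. Independent lists of these sizes would share 10.3 and 4.71 genes. Both comparisons use the same NT libraries, which alone correlates their fold changes. In 100 simulations the values of all 8 libraries, NT included, were drawn with no change and with noise independent between genes. Both comparisons then had few calls, with means of 0.08 and 0.11. Their mean of 0.03 shared calls was near 0 by construction and is no measure for lists of the observed size. The simulated fold changes correlated at a mean of 0.497 over genes (highest 0.627). The observed correlation of 0.581 lay within that range. Without short RNAs, KRT8 and KRT18 it was 0.583, and the highest simulated value was 0.537. These correlations are across genes, which are not independent replicates. The simulations held no noise shared between genes or libraries, so values beyond their ranges do not measure an overlap apart from the shared NT libraries. The covariance was 0.0751, beside a simulated mean of 0.0274 (highest 0.0413), and 0.0250 without short RNAs, KRT8 and KRT18, beside 0.00532 (highest 0.00596). The share of genes with the same sign was 67.8%, beside a simulated mean of 66.7% (highest 67.5%), and without those genes 67.9%, within the simulated range (highest 68.0%). The NT libraries were not divided between the comparisons, which would leave 1 for each, and part of the overlap may come from sharing them. The genes HNRNPA3, PLAGL2 and SLC35D1 passed in opposite directions; SLC35D1, chosen after its values were seen, had -0.36 ± 0.06 with LIN28 siRNA and 0.27 ± 0.06 with hnRNP A1 siRNA. Leaving out 1 of the 8 libraries gave from 56 shared calls (without LIN28 siRNA replicate 2) to 86 (without either replicate of both siRNAs), and fitting only the compared groups gave 32.

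hnRNP A1 siRNA against LIN28 siRNA tested directly where the single knockdowns differ. Beside the targets LIN28A (1.56 ± 0.06) and HNRNPA1 (-1.03 ± 0.06), the nerve growth factor receptor gene NGFR stood at 2.27 ± 0.935 FPKM with LIN28 siRNA and 8.79 ± 1.24 FPKM with hnRNP A1 siRNA (SD, n = 2; log2 fold change 1.61 ± 0.21, adjusted p = 0.018), TEX19 was higher with hnRNP A1 siRNA (1.10 ± 0.11), and the annexin gene ANXA1 was lower (-1.45 ± 0.17). CDH3 (0.98 ± 0.06), TJP1 (0.74), ITGA5 (0.81), FN1 (0.48), ACTA2 (0.40) and the myosin light chain kinase gene MYLK (0.59) were higher with hnRNP A1 siRNA, and CDS1 (-0.53), ELF3 (-0.33), TWIST1 (-0.50) and KRT7 (-0.43) were lower. FAS (0.69), CYFIP2 (0.54), PMAIP1 (0.44) and POLH (0.34) were the 4 of 30 p53 targets that were higher. HNRNPA3 (0.67) and HNRNPH3 (0.42) were higher and HNRNPA0 (-0.50), HNRNPUL1 (-0.31) and HNRNPA1L2 (-0.58) lower, PTBP3 was higher (0.43), and so were NRIP1 (0.39) and RET (0.48). Of the 39 interferon response genes, IFI44 (0.54) and IFI44L (0.76) were higher with hnRNP A1 siRNA, and the list did not pass camera (adjusted p = 0.14; median 0.07). ATF3 (-0.38) and H3C10 (-0.51) were lower and INSIG1 (0.52), PFKFB3 (0.74) and P4HA2 (0.41) higher. Short RNAs were called too: SNORA62 (145 and 137 FPKM) and SNORD94 (54.1 and 59.5 FPKM) were listed at 0 with LIN28 siRNA, and SNORA5B (166 and 95.4 FPKM), SNORA71D (61.6 and 71.4 FPKM) and SNORD22 (337 and 128 FPKM) at 0 with hnRNP A1 siRNA. Within groups, 147 zeros of short RNAs stood beside at least 10 FPKM in the replicate, so these zeros are not evidence of absence. In all, 501 genes were called, 319 higher and 182 lower with hnRNP A1 siRNA, and 94 differed by at least 1.5-fold. Of the 40 named genes that passed, 6 also passed without each library in turn: LIN28A, HNRNPA1 and 4 short RNAs. The other 34 missed the threshold without LIN28 siRNA replicate 1, and from 10 (without NT replicate 1) to 33 (without hnRNP A1 siRNA replicate 2) did so without other libraries (adjusted p up to 0.228). The count of calls ran from 7 without LIN28 siRNA replicate 1 to 237 without NT replicate 1, with 7 higher and 16 lower without LIN28 siRNA replicate 2, and was 14 when only the compared groups were fitted.

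Between the single knockdowns, let-7 targets were higher with hnRNP A1 siRNA than with LIN28 siRNA by camera (adjusted p = 0.019; median 0.13), with PLAGL2 at 0.86 ± 0.07 the 1 of 24 that passed (4 adjusted over the list alone), and cholesterol synthesis genes were higher (0.026; median 0.08, 1 of 24, 5 adjusted over the list alone). Ribosomal protein genes were lower (adjusted p = 5.2e-07; median -0.13), as were oxidative phosphorylation genes (0.026; median -0.07) and histone genes (0.026; median -0.25), with 0 of 77, 0 of 73 and 1 of 13 members lower. These 5 lists each had an adjusted p = 0.97 with an estimated correlation. Without LIN28 siRNA replicate 1 the median of the oxidative phosphorylation list turned positive. All 5 calls were lost without LIN28 siRNA replicate 1, let-7 targets and cholesterol synthesis each with an adjusted p = 0.13, ribosomal proteins with 0.12, oxidative phosphorylation with 0.66 and histones with 0.20. Without hnRNP A1 siRNA replicate 2 the let-7 and cholesterol calls (adjusted p = 0.071 each) and the histone call (0.080) were lost, without hnRNP A1 siRNA replicate 1 the oxidative phosphorylation call (0.83), which was also lost with quantile normalization (0.23), and PLAGL2 missed the threshold without LIN28 siRNA replicate 1 or either hnRNP A1 siRNA replicate (up to 0.066).

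Both siRNAs against LIN28 siRNA alone asked what lowering hnRNP A1 adds to lowering LIN28. Of 11686 genes, 8 were called. LGALS3BP was higher, at 67.2 ± 6.53 FPKM against 33.8 ± 0.301 FPKM (SD, n = 2; log2 fold change 0.97 ± 0.09, adjusted p = 0.031), as was CDH3 (0.67). HNRNPA1 (-0.86 ± 0.06), the ubiquitin-conjugating enzyme gene UBE2A (-0.59) and ATP6V1C1 (-0.55) were lower, SNORA62 was at 80.6 and 120 FPKM and listed at 0 with LIN28 siRNA alone, and SNORA5B and SNORA71D were listed at 0 with both siRNAs. Of these 8, the calls of SNORA5B and SNORA71D held without each library in turn; the other 6 were lost without LIN28 siRNA replicate 1, and from 3 to 5 of them without each of the other 7 libraries (adjusted p up to 0.276). The interferon response list was higher by camera (adjusted p = 2.0e-08; median 0.18, 0 of 39 passed, 10 adjusted over the list alone), with an adjusted p = 0.65 with an estimated correlation. Ribosomal protein genes were lower (adjusted p = 2.0e-08; median -0.12, 0 of 77), as were oxidative phosphorylation genes (0.012; median -0.07, 0 of 73), each with an adjusted p = 0.97 with an estimated correlation, and histone genes (0.012; median -0.18, 0 of 13; adjusted p = 0.93 with an estimated correlation). The oxidative phosphorylation median turned positive without LIN28 siRNA replicate 1. Without LIN28 siRNA replicate 1 the ribosomal (adjusted p = 0.11), oxidative phosphorylation (0.46) and histone calls (0.33) were lost, the oxidative phosphorylation call also with quantile normalization (0.20), and the histone call without replicate 2 of both siRNAs (0.12). The number of calls was 3 without LIN28 siRNA replicate 1, 4 without either hnRNP A1 siRNA replicate, 14 without LIN28 siRNA replicate 2, and 12 and 13 without replicates 1 and 2 of both siRNAs. It was 2 with no filter and 32 without genes listed at 0 in 1 library of a pair, and 1680 genes had an unadjusted p under 0.05. With the replicate number as a block it was 605, but the labels do not say that the numbers pair libraries.

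Both siRNAs against hnRNP A1 siRNA alone asked what lowering LIN28 adds to lowering hnRNP A1. LIN28A fell from 43.1 ± 0.0279 to 14.6 ± 0.728 FPKM (SD, n = 2; log2 fold change -1.50 ± 0.06, adjusted p = 0.00047), and the 1 other called gene was SNORD94, at 54.1 and 59.5 FPKM with hnRNP A1 siRNA and listed at 0 with both. The calls numbered 2 of 11686, with 204 genes at an unadjusted p under 0.05, and 7 to 12 without NT, hnRNP A1 siRNA or double-siRNA libraries: 7 without either NT replicate, 8 and 9 without hnRNP A1 siRNA replicates 1 and 2, and 8 and 12 without replicates 1 and 2 of both siRNAs. The interferon response list was higher by camera (adjusted p = 1.7e-12; median 0.09, 0 of 39 passed), with an adjusted p = 0.79 with an estimated correlation. Let-7 targets were lower (adjusted p = 0.0025; median -0.06, 0 of 24 passed), with an adjusted p = 0.97 with an estimated correlation; that call was lost without hnRNP A1 siRNA replicate 2 (0.15) or replicate 1 of both siRNAs (0.31).

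The interaction asked whether the effect of both siRNAs departs from the sum of the single effects on the log2 scale. Interferon-induced genes rose by less with both siRNAs than that sum. Equal rises in all 3 knockdown groups would by themselves give a negative interaction of about their size. Median rises of the 39 interferon response genes were 0.97, 1.04 and 1.2, and 0 of 39 passed between both siRNAs and either single siRNA. The rises were not exactly equal. With both siRNAs 35 of 39 were higher than with LIN28 siRNA (median 0.18) and 36 than with hnRNP A1 siRNA (median 0.09). The list passed camera in both (adjusted p = 2.0e-08 and 1.7e-12), but not with an estimated correlation (0.65 and 0.79). The interaction therefore cannot tell a joint effect of the siRNAs from a response shared by all 3 groups. IFI44 rose by 1.58 with hnRNP A1 siRNA and 1.51 with both, with an interaction of -1.12 ± 0.08 (adjusted p = 0.0079), and IFIT3 (-1.99 ± 0.19), OASL (-1.45 ± 0.12), IFIT1 (-1.35 ± 0.11) and XAF1 (-1.26 ± 0.10) had negative interactions, as did ACTA2 (-0.77 ± 0.10). Of the 39 interferon response genes, 13 passed (38 adjusted over the list alone), with a median interaction of -0.88. All 39 were negative, also without each library in turn, where the medians ran from -0.76 to -0.90. The list passed camera (adjusted p = 5.8e-51) and fry (0.0029), with an adjusted p = 0.071 with an estimated correlation. G1/S genes (adjusted p = 0.020; median -0.17, 0 of 39) and oxidative phosphorylation genes (0.034; median -0.09, 0 of 73) had negative interactions by camera, each with an adjusted p = 0.89 with an estimated correlation. The G1/S call was lost without NT replicate 1 (adjusted p = 0.59), LIN28 siRNA replicate 2 (0.61), hnRNP A1 siRNA replicate 2 (0.25) or replicate 1 of both siRNAs (0.26), and the oxidative phosphorylation call without NT replicate 2 (0.15), LIN28 siRNA replicate 1 (0.79), hnRNP A1 siRNA replicate 2 (0.72) or replicate 1 (0.052) or 2 (0.063) of both siRNAs. In all, 32 genes passed, 2 positive and 30 negative, but 11 of 26 and 12 of 31 were positive without NT replicates 1 and 2, 8 of 15 and 10 of 16 without replicates 1 and 2 of both siRNAs, and 2 of 6 without LIN28 siRNA replicate 1. The 32 were 5 short RNAs listed at 0 in some groups and 27 others, which were higher than NT in all 3 groups. The 2 positive ones were the short RNAs SNORA62 and SNORA20. The calls numbered 9 with no filter, 18 and 21 without hnRNP A1 siRNA replicates 1 and 2, and 21 without LIN28 siRNA replicate 2. The interferon response members that passed numbered 1 without LIN28 siRNA replicate 1 or replicate 2 of both siRNAs, 3 without replicate 1 of both siRNAs, 5 without LIN28 siRNA replicate 2 or hnRNP A1 siRNA replicate 1, 6 without NT replicate 1, 8 without hnRNP A1 siRNA replicate 2 and 8 with quantile normalization. Of the 12 named genes, IFI44 and 4 short RNAs passed without each library in turn.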

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

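All tests of explanations in this part were chosen after the results they measure had been seen; the interaction test itself was planned.

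The interaction of the siRNAs was tested for each gene, and it differed from 0 for 32 genes, 13 of them in the interferon response list. Apart from 5 short RNAs, these genes were higher than NT in all 3 groups, and their change with both siRNAs was below the sum of the single effects on the log2 scale. Equal rises in the 3 groups would give negative interactions too. The test therefore does not tell a joint effect of the siRNAs from a shared response. The interaction was -1.99 for IFIT3, -1.71 for IFITM3, -1.45 for OASL, -1.35 for IFIT1, -1.26 for XAF1, -1.12 for IFI44 and -0.77 for ACTA2. All 39 tested interferon response genes stayed negative without each library in turn, with medians from -0.76 to -0.90. IFI44 passed without each library in turn (adjusted p up to 0.0433). OASL missed the threshold without LIN28 siRNA replicate 1 or replicate 2 of both siRNAs, and IFIT1 and XAF1 without those or replicate 1 of both siRNAs (adjusted p up to 0.0668). IFIT3 missed it without any 1 of the 6 knockdown libraries (0.0980), IFITM3 without those or NT replicate 1 (0.191), and ACTA2 without any 1 of the 8 libraries (0.270). Of the 32 calls 2 were positive, beside 11 of 26 and 12 of 31 without NT replicates 1 and 2, 8 of 15 and 10 of 16 without replicates 1 and 2 of both siRNAs, and 2 of 6 without LIN28 siRNA replicate 1. The 32 calls became 6 without LIN28 siRNA replicate 1, 15 and 16 without replicates 1 and 2 of both siRNAs, 18 and 21 without hnRNP A1 siRNA replicates 1 and 2, and 21 without LIN28 siRNA replicate 2. The 13 became 1 without LIN28 siRNA replicate 1 or replicate 2 of both siRNAs, 3 without replicate 1 of both siRNAs, 5 without LIN28 siRNA replicate 2 or hnRNP A1 siRNA replicate 1, 6 without NT replicate 1, and 8 without hnRNP A1 siRNA replicate 2.

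Interferon response genes were higher in all 3 knockdown groups than in NT. A difference in scaling between libraries was argued against, because at least 35 of the 39 genes rose in each comparison with NT under quantile normalization and median ratio scaling. A single NT library standing apart was argued against too, because in all 39 genes both NT libraries lay below all 6 knockdown libraries. That does not cover a difference of the NT group as a whole. A response to the siRNA reagents or their delivery, apart from their targets, cannot be told apart from an effect of lowering LIN28 and hnRNP A1, because the labels describe 1 siRNA treatment per target and only 2 of the 39 genes differed between hnRNP A1 and LIN28 siRNA. The biological explanation, a rise that follows from lowering either target, stays open for the same reason.

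KRT8 and KRT18, keratin genes of luminal cells, were listed at 0 in NT replicate 2 beside 5853 and 3581 FPKM in NT replicate 1. Cells of another type in that library were argued against, because the other 8 luminal markers had a median log2 ratio of 0.0054 between the NT replicates (range -0.36 to 0.30). An upper limit on reads at a locus during abundance estimation may give a 0 for the most abundant genes, and KRT8 and KRT18 ranked 1 and 2 among protein-coding genes in the other 7 libraries. NT replicate 2 was not the deepest library, at 0.971 of the depth of NT replicate 1. LIN28 siRNA replicate 1, at 0.952 of that depth, had KRT8 at 6421 FPKM. The explanation by a limit on reads cannot be told apart from others here, because the reads of NT replicate 2 at these genes are not in the values. No biological explanation was tested, since the design sets no difference between replicates of a group.

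HNRNPA1P10 and HNRNPA1L2 fell together with HNRNPA1 in the cells given hnRNP A1 siRNA. Reads shared with HNRNPA1 may account for the fall of HNRNPA1P10: it fell by 0.93 and HNRNPA1 by 0.99 with hnRNP A1 siRNA, and the larger difference of the pair, with both siRNAs, was 1.54 standard errors. The standard error of the difference took both genes as independent, although they come from the same libraries. A small difference therefore does not establish shared reads. HNRNPA1L2 fell by 0.55 with hnRNP A1 siRNA (its call was lost without either NT or either hnRNP A1 siRNA replicate, adjusted p up to 0.080), a difference from HNRNPA1 of up to 4.47 standard errors; shared reads diluted by reads of its own cannot be told apart there from a smaller fall without shared reads. An action of the siRNA on transcripts of the copies themselves cannot be told apart from shared reads, because no copy fell by more than HNRNPA1 (the closest lay 0.0532 above it on the log2 scale).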

How the results depend on the processing

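Leaving out short RNAs and leaving out genes with a lone 0 were chosen after the values had been seen, and the other alternatives were planned. LIN28A and HNRNPA1 kept their direction and their side of the threshold under every alternative in the comparisons of their own siRNA with NT. HNRNPA1 in LIN28 siRNA against NT ran from -0.0047 (without LIN28 siRNA replicate 1, where it reversed) to 0.10 without 1 library, and passed in neither case. Below, counts of calls are given in the order LIN28 siRNA, hnRNP A1 siRNA and both siRNAs against NT, both against LIN28 siRNA, both against hnRNP A1 siRNA, the interaction, hnRNP A1 against LIN28 siRNA, and the overlap of the single knockdowns. Leaving out 1 library gave 68 to 152, 140 to 648, 100 to 363, 3 to 14, 2 to 12, 6 to 31, 7 to 237 and 56 to 86 calls; fewer samples estimate the spread, and the lone library of a group is assumed to vary like the other groups. Fitting only the groups compared gave 44, 86, 100, 10, 8, none for the interaction, which needs all groups, 14 and 32, with fewer samples to estimate the spread. A fold minimum of 1.5 gave by construction 110, 190, 156, 7, 2, 32, 94 and 74. Both siRNAs against LIN28 siRNA gave 2 calls with no filter, 17 with a mean of at least 5 FPKM, 24 with robust variance, 21 without short RNAs and 32 without genes with a lone 0; the interaction gave 9 with no filter; the cause was not tested. Both siRNAs against hnRNP A1 siRNA gave 1 without short RNAs, because 1 of its 2 calls was the short RNA SNORD94. The replicate number as a block gave 1726, 2924, 2363, 605, 2, 113 and 2251 calls, an overlap of calls between single knockdowns of 844, and 7 lists for both siRNAs against LIN28 siRNA. The labels do not say that the numbers pair libraries. Differences from the group mean correlated across genes between groups at -0.050 to 0.157 (Pearson, or 0.374 to 0.607 without short RNAs). The Spearman range was 0.303 to 0.713. This is a hint from the data that replicates of 1 number share something. Leaving out 1 library would set part of such a difference between the groups compared, so whether it ended a call cannot be told. Of the 19 planned lists tested, 0 were called with an estimated correlation in each of the 7 comparisons, and fry called 1 list (interferon response) in each comparison with NT and in the interaction, and 0 in the other 3. Leaving out 1 library gave 2 to 7, 4 to 6, 5 to 7, 3 to 7, 2 to 8, 2 to 7 and 0 to 7 lists. Without LIN28 siRNA replicate 1 the oxidative phosphorylation list changed its direction by median or test, with medians of 0.0179 (LIN28 siRNA against NT), 0.0158 (both against LIN28 siRNA), -0.0279 (interaction) and 0.0111 (hnRNP A1 against LIN28 siRNA). The other ends of the range without 1 library were 0.172, -0.148 and -0.154 without LIN28 siRNA replicate 2 for the comparisons, and -0.167 without hnRNP A1 siRNA replicate 1 for the interaction; the cause was not tested. For the single genes and lists that were named and had passed, apart from LIN28A and HNRNPA1 in the comparisons with NT and the counts above, 3190 results under alternatives kept direction and side of the threshold, 1020 kept the direction and missed the threshold, and 4 reversed, those of the oxidative phosphorylation list. Named genes and lists that had not passed are not in these counts. Absolute depth is not given, so what depth limits cannot be stated beyond the filter of 1 FPKM.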

Other observations

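The gene lists, their genes and the transcript test in this part were chosen after the values had been seen, and leaving out libraries was not run for them.

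Genes of class I antigen presentation, which display peptides to T cells, rose in the knockdown groups beside the interferon response genes. B2M, the light chain of the class I complex, rose by 0.81 with LIN28 siRNA, 1.11 with hnRNP A1 siRNA and 1.13 with both (log2, limma), and NLRC5, a transactivator of class I genes, rose by 0.82, 1.06 and 1.10. The peptide-trimming gene ERAP1 rose by 0.39, 0.68 and 0.60, and PSME2 by 0.36, 0.32 and 0.34. ERAP2 rose by 0.63 with hnRNP A1 siRNA and 0.67 with both, and had 0.37 with LIN28 siRNA, which did not pass (limma adjusted p = 0.073); the direct test of hnRNP A1 against LIN28 siRNA did not pass (0.26, adjusted p = 0.126). Of the 7 measured members of the 17 listed, 4, 5 and 5 rose (7 in each adjusted over the list alone), with medians of 0.37, 0.63 and 0.60. The list had a camera adjusted p of 2.5e-07, 5.0e-07 and 1.9e-08, and of 0.041, 0.045 and 0.031 with an estimated correlation. The p-values of lists in this part were adjusted over only the 3 lists tested here, which were picked after the interferon rise had been seen, so they cannot be set beside those of the 19 planned lists. HLA-A, HLA-B, HLA-C, HLA-E, HLA-F, TAP1, TAP2, TAPBP, PSMB8 and PSMB9 were listed at 0 in all 8 libraries. The annotation and the options of the abundance estimation are not given, so these zeros are not evidence that the genes were not expressed.

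Among 16 measured genes of RNA sensing and its signalling, 3, 5 and 5 rose in the comparisons with NT and 1 fell in each. TRIM21 rose by 0.88, 0.97 and 1.01, TRIM14 by 0.53, 0.80 and 0.76, and PNPT1 by 0.55, 0.65 and 0.71. With hnRNP A1 siRNA and both siRNAs ZC3HAV1 rose by 0.38 and 0.53 and IL10RB by 0.34 and 0.29, and with LIN28 siRNA they had 0.33 (limma adjusted p = 0.071) and 0.12 (0.30). Neither passed in the direct test of hnRNP A1 against LIN28 siRNA (0.05 and 0.22, adjusted p = 0.71 and 0.083). MAVS, the mitochondrial adaptor of RNA sensing, fell by 0.42, 0.46 and 0.45. The list had a camera adjusted p of 0.091, 0.023 and 0.010, and of 0.34, 0.21 and 0.17 with an estimated correlation. IFNB1, the interferon beta gene, was below the filter and not tested, at 0.209 and 0.191 FPKM in NT, 0.930 and 1.39 with LIN28 siRNA, 0.731 and 0.754 with hnRNP A1 siRNA and 1.07 and 1.32 with both. Of 17 subunits of the vacuolar proton pump, 0, 2 and 3 fell in the comparisons with NT, ATP6V1C1 and ATP6V1D (-0.37 with hnRNP A1 siRNA and -0.27 with both) and, with both siRNAs, ATP6V0A1 (-0.28). The list had a camera adjusted p of 0.40, 0.093 and 0.044, and 0.204 in the last with an estimated correlation. Another list, of interferons and chemokines, had too few measured members for a test.

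Transcript shares were tested for 7312 transcripts of 3116 genes with limma, and genes with a changed share numbered 0, 2 and 3 in the comparisons with NT (603, 791 and 754 transcripts at an unadjusted p under 0.05). The RPS24 transcript NM_001026 held 89.0% ± 1.74 of the gene's FPKM in NT, 80.4% with LIN28 siRNA (not passing), 74.6% ± 1.86 with hnRNP A1 siRNA (SD, n = 2; limma adjusted p = 0.0087) and 76.0% ± 1.62 with both siRNAs (0.023). The RBM10 transcript NM_005676 held 24.4% ± 6.48 in NT, 21.9% with LIN28 siRNA, 3.83% ± 0.203 with hnRNP A1 siRNA (limma adjusted p = 0.0087) and 17.6% with both siRNAs. Of all transcripts tested, 0 passed in the direct test of both siRNAs against hnRNP A1 siRNA, and 2 passed in the interaction. In hnRNP A1 siRNA against LIN28 siRNA 3 passed, among them this RBM10 transcript (change in log2 ratio -2.16, limma adjusted p = 0.020). The glucocorticoid receptor transcript NM_001018076 of NR3C1 held 37.1% in NT, 21.1% with LIN28 siRNA, 19.1% with hnRNP A1 siRNA and 15.3% with both siRNAs, of which only the last passed against NT (limma adjusted p = 0.023). The SMUG1 transcript NM_001243788 held 11.1%, 5.38%, 5.72% and 3.62%, and again only the last passed (0.038). With the replicate number as a block that call missed the threshold (limma adjusted p = 0.074). Between both siRNAs and LIN28 siRNA only a BACE1 transcript passed, so neither NR3C1 nor SMUG1 passed in a direct test with a single siRNA. For ENAH, a gene with splicing-regulated forms, the transcript NM_018212 held 16.6% ± 0.457 in NT and 29.5% ± 0.287 with LIN28 siRNA, which did not pass (limma adjusted p = 0.064), nor did 22.4% with hnRNP A1 siRNA (0.24) or 25.3% with both (0.16). The PKM transcript NM_002654 held 93.0% in NT, 93.5% with LIN28 siRNA, 93.0% with hnRNP A1 siRNA and 92.7% with both.

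Zeros beside high values were frequent among short RNAs: 149 values of 0 stood beside at least 10 FPKM in the other library of the group, 147 of them in short RNAs and 2 in KRT8 and KRT18. Some lists had a median, mean and tests of differing sign, 3, 3, 3, 3, 5, 1 and 2 lists in LIN28 siRNA, hnRNP A1 siRNA and both siRNAs against NT, both against LIN28 siRNA, both against hnRNP A1 siRNA, the interaction and hnRNP A1 against LIN28 siRNA, and camera called 0 of these. They were mainly the estrogen response, mesenchymal and luminal lists in the comparisons with NT. The luminal and epithelial lists both include KRT8 and KRT18, which were listed at 0 in NT replicate 2. In LIN28 siRNA, hnRNP A1 siRNA and both siRNAs against NT the luminal means were 1.28, 1.13 and 1.14. The epithelial means were 0.41, 0.43 and 0.39, beside medians of 0.05, 0.07 and 0.03.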
